A study of Homo sapiens with 5 samples.

How the data were processed

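Poly-A RNA was measured in 5 libraries of Rh41, a human alveolar rhabdomyosarcoma cell line. Per the labels, 2 libraries came from cells given a scrambled siRNA (replicates 1 and 3) and 3 from cells given an siRNA against H3F3A (replicates 1, 2 and 3), each for 48 hours, with Lipofectamine RNAiMAX as the carrier. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

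Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured on poly-T beads, fragmented and primed with random hexamers, and libraries were made with a NEBNext Ultra kit. That kit does not mark the strand of a transcript, and the stranded columns of the files split the reads evenly, with 49.9% to 50.1% in the first of them. The submitters' processing notes name CASAVA, bcl2fastq, STAR version 2.5, HTSeq version 0.6.1, DESeq2 and the hg19 build, without saying which tool made which file. The deposited values are raw read counts per gene in the layout of STAR's gene tables, with 1 unstranded and 2 stranded count columns. The unstranded counts were used. The 4 summary lines at the top of each file name no gene and were kept out of library sizes and tests. Of all reads in a file, 4.84% to 5.48% were unmapped and 6.28% to 6.42% mapped to several places. A further 9.17% to 10.2% overlapped no annotated exon, and 4.45% to 4.56% were ambiguous between genes.

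Gene symbols are printed as the files give them, except that H3F3A and H3F3B are used for the rows named H3-3A and H3-3B. The files hold 43714 gene rows, of which 4791 are numbered copies of 2420 genes. KIR3DL3, for example, has 47 rows. So many copies point to a reference with alternate haplotypes rather than to plain hg19, so no genome coordinates are given. Reads of a gene with copies can be split or lost as multimapping, and values of such genes are uncertain. The numbered copies held 0.09% to 0.0963% of the assigned counts. Reads from overlapping genes on opposite strands cannot be told apart in the unstranded counts.

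Assigned counts ran from 28493573 to 30705963 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group with its default minimum count of 10 and minimum total of 15, which left 15859 genes. Libraries were scaled by TMM, a quasi-likelihood model was fitted with robust=TRUE, and H3F3A siRNA was compared with scrambled siRNA without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold minimum. The estimated biological coefficient of variation was 6.53%. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values are counts scaled by the TMM library size in the usual way of edgeR.

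On simulated data with the means and depths of these libraries, in which 200 genes were changed, the test ran on 15618 genes and recovered 66% of genes changed by 0.4 log2 and 95% of those changed by 1 log2. Unchanged genes made up 8% of its calls. With no gene changed it made 1 call, and also 1 with a GC trend in 1 control library and no correction. When 1 gene list was raised, 2 lists passed the list test described below. The simulations, here and below, drew each gene independently, without the deviations that genes of a library share. Their rates of false calls may therefore be too low for these data.

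Before the data were examined, 30 gene lists were fixed to fit the cell type and the treatment: H3.3 histone genes, H3.3 chaperones and remodellers, canonical replication histones, PAX3-FOXO1 targets, myogenic regulators, muscle differentiation, G2/M cell cycle, G1/S and DNA replication, actin cytoskeleton and focal adhesion, integrins and cell adhesion receptors, extracellular matrix, proteases and invasion, epithelial-mesenchymal transition regulators, interferon-stimulated genes, p53 targets, integrated stress response, cholesterol synthesis, hypoxia and glycolysis, immediate early and AP-1, YAP/TEAD targets, polycomb and histone methylation machinery, HOX genes, neuronal genes, ribosomal proteins, oxidative phosphorylation, markers of fibroblasts, epithelium, endothelium and immune cells, and a further list. That list and some genes that the naming rule gave are not reported here. The 29 lists with at least 5 measured members were tested against all other genes with camera (limma 3.58.1, by edgeR's method for count data) at a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and fry, which tests whether the members move one way without a comparison to other genes, were alternatives. List means are mean log2 fold changes of the measured members.

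The genes named were set by a rule fixed at the same time. They are H3F3A, H3F3B and MCAM; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 8 CPM and every H3F3A siRNA library on the same side of both scrambled libraries; and in each list up to 4 called members with the smallest p or, where none was called, up to 2 members given as values. MCAM was remembered as a gene the study followed up, probably chosen on these libraries, and was held out of the lists.

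Alternatives planned at the same time were RLE and upper-quartile scaling, no filter on low counts, a minimum mean of 5 CPM, robust=FALSE, each stranded column, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and a minimum absolute log2 fold change of 1. Others were chosen after the data were seen. In the GC correction, each library's deviation from the mean log2 CPM of a gene was smoothed over the GC content of the gene's longest GENCODE release 29 transcript (lowess, span 0.5, prior count 2) and removed as an offset. By symbol, 27120 rows matched a transcript, and 90.7% of tested genes and 97.2% of called genes had a GC value, which left 14377 genes in that fit. The same genes without the correction, the correction with scrambled replicate 1 left out, and numbered copies summed into 1 row were also run. On simulated counts of 14210 genes with a GC trend in 1 control library, the corrected fit recovered 62.4% of genes changed by 0.4 log2 and 95.8% of those changed by 1 log2.

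No libraries of a group agreed within sampling noise: the chi-square per degree of freedom between libraries of a group ran from 3.57 to 13.7, so each was counted as 1 replicate. By this measure scrambled replicate 3 lay farther from scrambled replicate 1 (13.7) than from H3F3A siRNA replicates 1, 2 and 3 (12.9, 6.04 and 7.93). Its correlation in log2 CPM was 0.9939 with scrambled replicate 1, and 0.9932, 0.9943 and 0.9944 with those 3 libraries. Rows of mitochondrial protein-coding genes were not analysed here. Python 3.11.15 and matplotlib 3.10.9 were used for GC content and figures.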

Results

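The series addresses the part played by the histone variant H3.3 in metastasis of alveolar rhabdomyosarcoma, a soft tissue tumour with features of immature skeletal muscle. Rh41 is an established line of the fusion-positive form, which is driven by the PAX3-FOXO1 fusion protein. H3.3 is encoded by both H3F3A and H3F3B. Rh41 cells received a scrambled siRNA (n = 2 libraries) or an siRNA against H3F3A (n = 3 libraries) for 48 hours, and the design implies 1 comparison between them. The scrambled libraries held 30353965 and 29776931 counts assigned to genes, and the H3F3A siRNA libraries held 29421440, 28493573 and 30705963.

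H3F3A transcripts fell 29.7-fold, while those of H3F3B, the other gene for the same protein, passed no test. H3F3A stood at 281 ± 17.7 CPM (SD, n = 2) in scrambled libraries and at 9.47 ± 0.97 CPM (SD, n = 3) after H3F3A siRNA, so 3.36% of the level remained (log2 fold change -4.89, SE 0.0923, edgeR adjusted p = 9.04e-21). The raw counts were 8571 and 7983 against 280, 304 and 264 in the H3F3A siRNA libraries. H3F3B stood at 821 ± 25.6 CPM in scrambled libraries and 819 ± 28 CPM after H3F3A siRNA, a log2 fold change with a 95% interval of -0.15 to 0.14 (adjusted p = 0.988). H3F3B had 2.92 times the CPM of H3F3A in scrambled libraries, a ratio of reads without correction for transcript length. The summed CPM of both genes, which is likewise a sum of reads and leaves out those counted under H3P6, went from 1102 ± 43.3 to 828 ± 27, or 75.1% of the scrambled reads. H3P6, a processed pseudogene of H3F3A, fell 31.4-fold, and its counts per 100 H3F3A counts were 17.1 and 17.3 in scrambled libraries and 16.4, 15.1 and 17.4 after H3F3A siRNA. Near-identical sequences can share reads, so the H3P6 value is uncertain. Of the 3 measured H3.3 histone genes, H3F3A alone was called, also when adjusted over the list alone, and the list was too short for the list test.

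**Figure D1:**
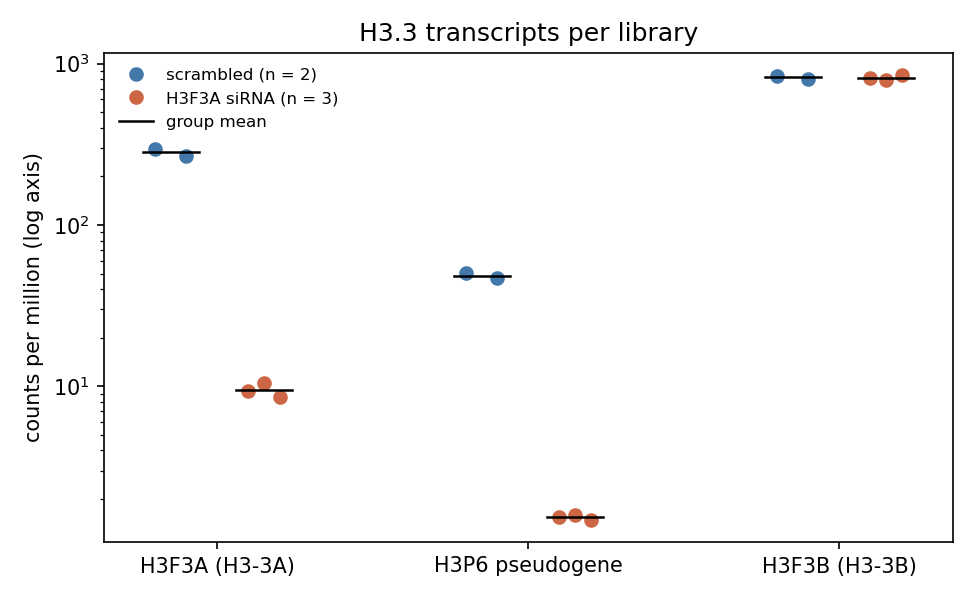
CPM (log axis) of H3F3A, its pseudogene H3P6 and H3F3B in each scrambled library (n = 2) and each H3F3A siRNA library (n = 3); points are libraries and black lines are group means. H3F3A lies at 269 and 294 CPM in scrambled libraries and at 8.54 to 10.5 CPM after H3F3A siRNA, while H3F3B lies between 791 and 847 CPM in all libraries.

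Counting H3F3A, 507 of 15859 genes tested were called, 427 lower and 80 higher after H3F3A siRNA (edgeR quasi-likelihood test, adjusted p under 0.05). The changes were small. The median absolute log2 fold change of called genes was 0.399, and 7 genes fell and 12 rose by at least 1 log2. The share of called genes that fell was 84.2% (exact 95% binomial interval over genes 80.8% to 87.3%), and with upper-quartile scaling it was 73.6%, from 323 lower and 116 higher.

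These counts depend on single libraries. Without scrambled replicate 1, 82 genes fell and 20 rose, and without scrambled replicate 3, 1737 fell and 744 rose. Without H3F3A siRNA replicate 1, 9 fell and 6 rose, without replicate 2, 153 fell and 24 rose, and without replicate 3, 253 fell and 55 rose. Scrambled replicate 1 stood apart from the other libraries in a trend over GC content. Its log2 CPM relative to the mean of all libraries rose by 0.143 for each 10 points of GC content, against -0.0059 in scrambled replicate 3 and -0.059, -0.0385 and -0.04 in the H3F3A siRNA libraries. In the top GC class the H3F3A siRNA libraries also lay below scrambled replicate 3, at -0.112, -0.0687 and -0.0827 against -0.0002. A smaller GC trend thus also ran between the groups. The rank correlation of log2 fold change with GC content across genes, which are not independent, was -0.52. Of the fallen genes with a GC value, 68.5% lay in the top 2 of 10 GC classes. With each library's trend removed, an alternative chosen after the data were seen, 197 genes fell and 85 rose, and 149 falls and 43 rises were called both ways. With scrambled replicate 1 left out of that fit as well, 56 genes fell and 16 rose.

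**Figure D2:**
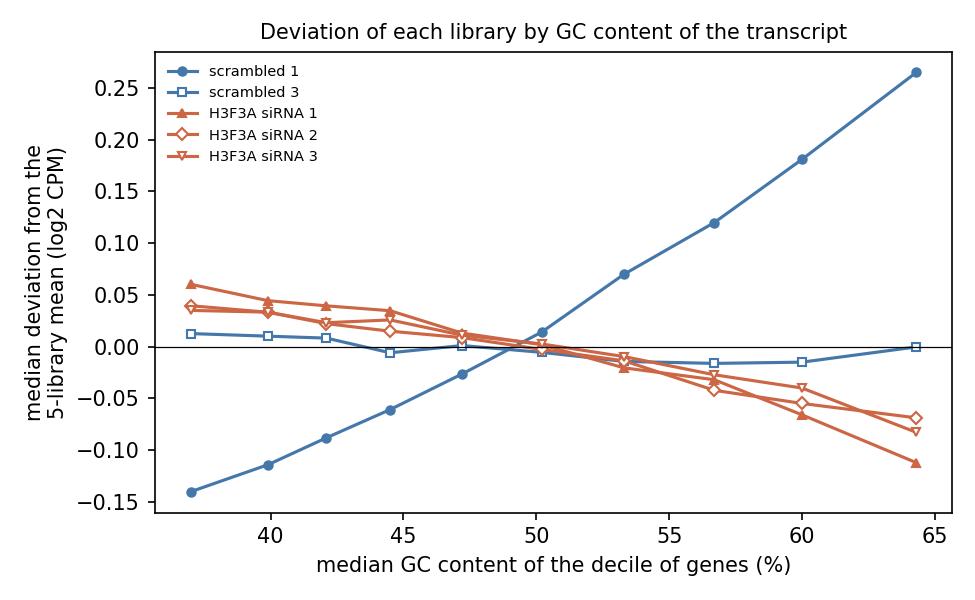
Median deviation of each library from the mean of all 5 libraries (log2 CPM) in 10 classes of genes ordered by GC content of the transcript; each line is a library, blue for scrambled and orange for H3F3A siRNA. Scrambled replicate 1 runs from -0.14 in the class with the lowest GC content to 0.265 in the highest, and the other libraries stay between -0.112 and 0.0603.

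Among called genes with a mean of at least 8 CPM, the 10 largest rises ran from 1.42-fold to 1.65-fold. SCN3B, a beta subunit of voltage-gated sodium channels, rose 1.65-fold from 14 ± 0.0573 CPM (SD, n = 2) to 23.1 ± 0.814 CPM (SD, n = 3; adjusted p = 0.000163). IL1RAPL2, a synaptic member of the interleukin-1 receptor family, and PYGM, the glycogen phosphorylase of muscle, each rose 1.56-fold. KCNC2, a voltage-gated potassium channel, rose 1.54-fold, and FCRLA, an Fc receptor-like protein, rose 1.52-fold from 95.1 to 145 CPM (adjusted p = 0.000163). The giant sarcomere protein TTN rose 1.45-fold, the secreted protein C1QTNF3 1.42-fold, the ephrin receptor EPHA3 1.48-fold, the retinal matrix proteoglycan IMPG2 1.52-fold and the atypical cadherin FAT3 1.54-fold. With GC correction, FAT3 (adjusted p = 0.0606) and TTN (adjusted p = 0.086) were not called, though their log2 fold changes moved little. They went from 0.619 to 0.575 for FAT3 and from 0.538 to 0.488 for TTN.

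Among called genes with a mean of at least 8 CPM, the largest falls after H3F3A and H3P6 ran from 1.56-fold to 1.72-fold. DMBT1, a secreted scavenger receptor glycoprotein, fell 1.72-fold from 43.1 ± 1.78 CPM (SD, n = 2) to 25.1 ± 0.516 CPM (SD, n = 3; adjusted p = 8.23e-06). DYSF, the dysferlin of muscle membrane repair, fell 1.68-fold from 136 ± 7.79 to 81.1 ± 3.08 CPM (adjusted p = 5.85e-06). DLK1, an imprinted non-canonical Notch ligand, fell 1.69-fold, and INHBE, an inhibin beta subunit, fell 1.66-fold. CPZ, a secreted carboxypeptidase, and JSRP1, a protein of the sarcoplasmic reticulum junction, each fell 1.58-fold, and the deubiquitinase OTUD1 fell 1.56-fold. The log2 fold change of JSRP1 was -0.66, and -0.31 with GC correction, and its call was lost without H3F3A siRNA replicate 1 and with GC correction when scrambled replicate 1 was also left out. SEMA6B, a transmembrane semaphorin and the most abundant of these genes, fell 1.65-fold from 2210 ± 237 to 1340 ± 246 CPM (adjusted p = 0.00347), and with GC correction it was not called (adjusted p = 0.149). SCN3B, IL1RAPL2, KCNC2, FCRLA, DMBT1, DYSF, INHBE, CPZ, H3P6 and, from the matrix list, LOXL2 were called in all 18 alternatives in which genes were tested. Of the 66 called genes that the naming rule gave other than H3F3A and MCAM, 26 were still called without scrambled replicate 1 and 39 with GC correction, and all kept their direction. Without H3F3A siRNA replicate 1 the 10 genes called in all alternatives were still called and the other 56 lost their call. The groups did not overlap in any of the 507 called genes, so leaving out a library could hardly turn a direction.

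**Figure D3:**
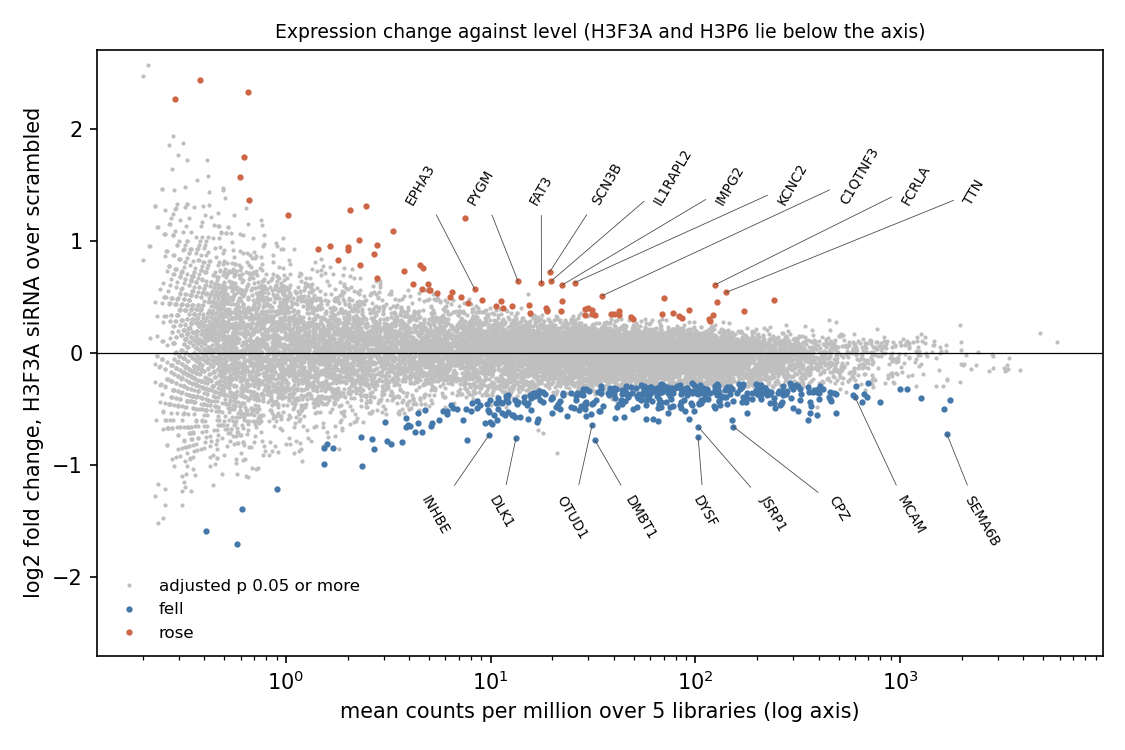
Log2 fold change after H3F3A siRNA (3 libraries) over scrambled siRNA (2 libraries) against mean CPM (log axis) for 15859 genes; coloured points passed the edgeR test, and the genes with the largest changes by the fixed rule and MCAM are named, except H3F3A and H3P6, which lie below the axis. Called genes number 427 below 0 and 80 above 0, and most lie within 1 log2 of 0.

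MCAM, a cell adhesion molecule of the immunoglobulin family that was remembered as a gene the study followed up, fell 1.31-fold, from 701 ± 42.7 CPM (SD, n = 2) to 534 ± 6.46 CPM (SD, n = 3; log2 fold change -0.39, SE 0.0748, adjusted p = 0.0055). It was probably chosen on these libraries, so its fall is not independent evidence. With GC correction the log2 fold change was -0.32 (adjusted p = 0.00339). The call was lost without H3F3A siRNA replicate 1 (adjusted p = 0.0848) and with GC correction when scrambled replicate 1 was also left out (adjusted p = 0.0512).

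Of 29 gene lists tested, 9 passed the threshold, 8 toward lower and 1 toward higher expression (camera at the preset correlation). The p-values at the preset correlation set genes against genes and do not measure the spread between the 5 libraries, however small they are. No list passed by camera with an estimated correlation (smallest adjusted p = 0.39, with 2 lists under an unadjusted p of 0.05) or by fry (smallest adjusted p = 0.077, with 12 lists under an unadjusted p of 0.05). With an estimated correlation, camera takes its degrees of freedom from the 5 libraries rather than from the genes. Few are left after 2 groups are fitted, so a list could hardly pass after adjustment. A missed threshold in that test, here and for the lists below, therefore cannot tell whether correlated members explain a result. Without scrambled replicate 3, 5 lists passed at the preset correlation. Members of the lists reported here that were called with GC correction but not without it, named after their values were seen, were SIX2, ATP2A1 and HOXD9, which rose, and CAPN2, NRCAM, SPARC, GADD45A, HSPA5, DUSP6 and SPRED1, which fell.

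The extracellular matrix list passed toward lower expression at the preset correlation (mean log2 fold change -0.229, camera adjusted p = 1e-11), with an adjusted p = 0.39 with an estimated correlation and 0.087 by fry. Of 49 measured members 12 fell, none rose and 37 were not called, and 24 fell when adjusted over the list alone. The collagen cross-linking enzymes LOXL2 and LOXL1 fell 1.51-fold and 1.45-fold, from 444 to 294 CPM and from 220 to 151 CPM. The matricellular protein CCN1 fell 1.34-fold, and COL18A1, a basement membrane collagen, fell 1.45-fold. With GC correction the log2 fold change of LOXL1 went from -0.54 to -0.26 and that of COL18A1 from -0.54 to -0.26, and without scrambled replicate 1 COL18A1 was not called. With GC correction the list mean was -0.166 (camera adjusted p = 3.3e-11, and adjusted p = 0.33 with an estimated correlation) and 9 members fell.

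The lists of cell adhesion, invasion and YAP/TEAD targets also passed toward lower expression, with means closer to 0. Among 45 integrins and cell adhesion receptors, 5 fell, 1 rose and 39 were not called, and adjusted over the list alone 8 fell and 3 rose (mean -0.08, camera adjusted p = 0.0072, and adjusted p = 0.39 with an estimated correlation). The receptor phosphatase PTPRF fell 1.29-fold, the laminin receptor subunit ITGA6 and the adhesion molecule L1CAM each fell 1.28-fold, and the protocadherin PCDH9 rose 1.38-fold. With GC correction ITGA6 alone of these was called, and the list mean was -0.07. In the list of proteases and invasion, 6 of 45 members fell and none rose (7 adjusted over the list alone; mean -0.09, camera adjusted p = 0.011, and adjusted p = 0.39 with an estimated correlation). CTSD, the lysosomal protease cathepsin D, fell 1.45-fold, the plasminogen activator PLAT 1.29-fold, the metalloprotease ADAM12 1.34-fold and the protease inhibitor TIMP1 1.35-fold, so the fallen members include an inhibitor of matrix breakdown. The log2 fold change of CTSD went from -0.53 to -0.32 with GC correction. YAP/TEAD targets fell in 3 of 23 members (4 adjusted over the list alone; mean -0.11, camera adjusted p = 0.0087, and adjusted p = 0.39 with an estimated correlation). These were CCN1, the receptor kinase AXL at 1.29-fold and FJX1 at 1.26-fold, and FJX1 was not called with GC correction (adjusted p = 0.472). Without scrambled replicate 3 these lists no longer passed, with adjusted p = 0.325 for adhesion receptors, 0.0904 for proteases and 0.359 for YAP/TEAD targets.

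**Figure D4:**
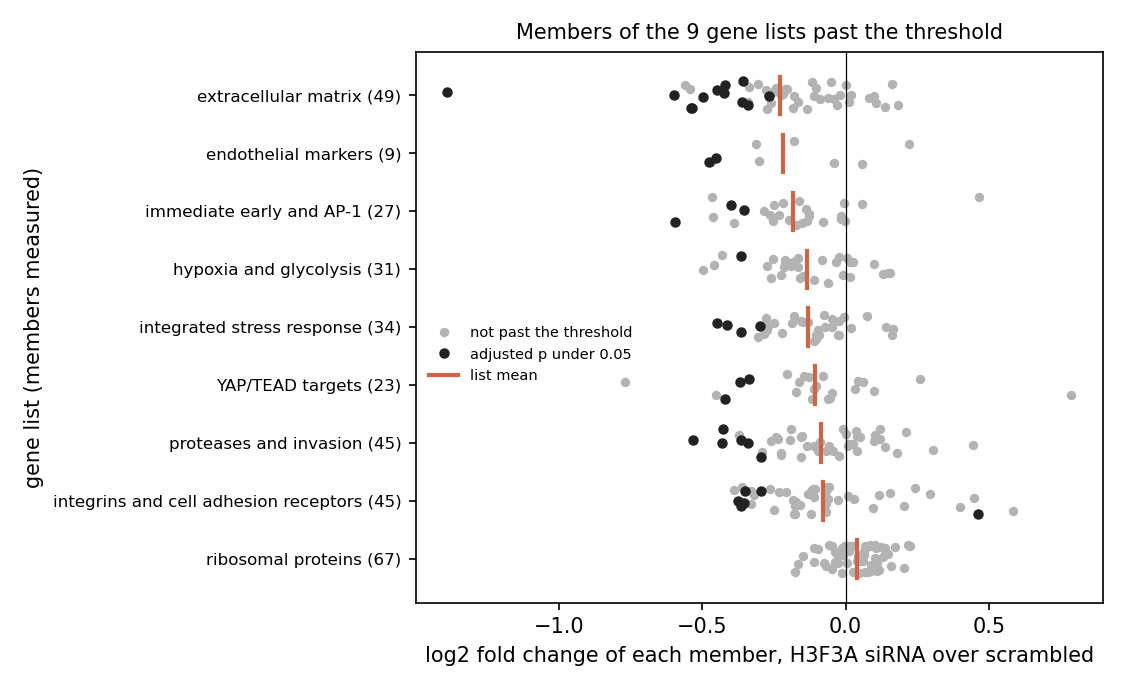
Log2 fold change of each measured member of the 9 gene lists past the threshold, H3F3A siRNA (3 libraries) over scrambled (2 libraries); black points passed the test gene by gene, grey points did not, and orange bars are list means. The list means run from -0.229 for extracellular matrix to 0.0411 for ribosomal proteins.

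The lists of the integrated stress response, immediate early genes, and hypoxia and glycolysis were also lower. Of 34 genes of the integrated stress response 4 fell and none rose (9 adjusted over the list alone; mean -0.13, camera adjusted p = 4.2e-05, and adjusted p = 0.39 with an estimated correlation). The amino acid transporter SLC7A5 fell 1.36-fold, the endoplasmic reticulum proteins SDF2L1 and PDIA4 fell 1.33-fold and 1.23-fold, and the angiogenic factor VEGFA fell 1.29-fold. Of 27 immediate early and AP-1 genes 3 fell, none rose, and 25 lay below 0 (11 fell when adjusted over the list alone; mean -0.18, camera adjusted p = 7.6e-06, and adjusted p = 0.39 with an estimated correlation). They were the AP-1 subunit FOSL1 at 1.51-fold, the ETS factor ETV4 at 1.28-fold and the nuclear receptor NR4A1 at 1.32-fold. In the list of hypoxia and glycolysis, 1 of 31 genes fell, VEGFA, which the stress list also holds (5 adjusted over the list alone; mean -0.13, camera adjusted p = 0.0067, and adjusted p = 0.39 with an estimated correlation). With GC correction the means were -0.10 for the stress response, -0.11 for immediate early genes and -0.11 for hypoxia and glycolysis, and all 3 lists passed at the preset correlation but had an adjusted p = 0.33 with an estimated correlation. SDF2L1 (adjusted p = 0.137), ETV4 (adjusted p = 0.251) and NR4A1 (adjusted p = 0.198) were not called with GC correction, and the log2 fold change of SLC7A5 went from -0.45 to -0.28.

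The lists of muscle and lineage genes did not pass. Among 49 genes of muscle differentiation 4 fell, 3 rose and 42 were not called (mean -0.04, camera adjusted p = 0.69). PYGM and TTN rose, while the sarcoglycan SGCA and the myosin light chain MYL4 fell 1.37-fold and 1.36-fold, and the log2 fold change of SGCA went from -0.45 to -0.25 with GC correction. Adjusted over the list alone 6 fell and 5 rose. Of 20 myogenic regulators, TCF3, an E-protein partner of MYOD1, fell 1.24-fold and EYA4, a transcriptional cofactor of myogenesis, rose 1.24-fold (camera adjusted p = 0.94; 2 fell and 1 rose adjusted over the list alone), and neither was called with GC correction. Of 26 PAX3-FOXO1 targets 1 fell and 2 rose (camera adjusted p = 0.66; 2 fell and 3 rose adjusted over the list alone). The receptor kinase FGFR4 fell 1.41-fold from 1980 ± 283 to 1410 ± 20 CPM (adjusted p = 0.00257), the transcription factor TFAP2B rose 1.41-fold from 56.8 ± 0.456 to 79.8 ± 1.57 CPM (adjusted p = 0.00133), and PDGFRA rose 1.45-fold at low abundance. PDGFRA was called in 7 of 18 alternatives. With GC correction it was not called (adjusted p = 0.0997), though its log2 fold change went only from 0.532 to 0.469. The log2 fold change of FGFR4 went from -0.50 to -0.29 with GC correction, and its call was lost when scrambled replicate 1 was also left out.

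Neither cell cycle list passed before GC correction. Of 49 genes of G1/S and DNA replication 2 fell (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.94, with a mean below 0 and a median above 0). CCND1, the cyclin of G1, fell 1.44-fold from 109 ± 2.17 to 75.6 ± 4.06 CPM (adjusted p = 0.000839), and the replication licensing factor CDT1 fell 1.28-fold, though not with GC correction (adjusted p = 0.358). None of 50 genes of the G2/M list was called, also when adjusted over the list alone. CDC20 had a log2 fold change of -0.22 (adjusted p = 0.152) and AURKB of -0.19 (adjusted p = 0.192). The G2/M list did not pass without the GC correction (mean -0.02, camera adjusted p = 0.78) but passed with it (mean -0.05, adjusted p = 0.004), with an adjusted p = 0.33 with an estimated correlation.

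Of 57 genes of the actin cytoskeleton and focal adhesion 4 fell and none rose (9 adjusted over the list alone; camera adjusted p = 0.13). They were VASP at 1.29-fold, TAGLN at 1.44-fold, PDLIM7 at 1.25-fold and ACTN1 at 1.22-fold, of which VASP, at a log2 fold change of -0.37 and -0.23 after correction, and ACTN1 were also called with GC correction. ACTN1 was called in 8 of 18 alternatives.

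The lists of chromatin genes did not pass. None of 13 H3.3 chaperones and remodellers was called, also when adjusted over the list alone (mean 0.07, camera adjusted p = 0.25), and the remodeller ATRX and UBN2, a HIRA complex subunit, had log2 fold changes of 0.26 (adjusted p = 0.167) and 0.25 (adjusted p = 0.19). Of 14 canonical replication histones measured from the 25 listed, H2AC6, at a mean of 6.12 CPM, fell 1.46-fold. It was the list's 1 call, also when adjusted over the list alone (camera adjusted p = 0.54). Poly-T capture takes up only transcripts with a poly-A tail, so histone transcripts without one are not covered. In the polycomb and histone methylation machinery 2 of 33 genes fell, PHF19 at 1.27-fold and the H3K79 methyltransferase DOT1L at 1.24-fold (2 adjusted over the list alone; camera adjusted p = 0.95, with a mean below 0 and a median above 0). DOT1L was not called with GC correction (adjusted p = 0.364).

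The remaining lists did not pass, apart from endothelial markers and ribosomal proteins. No interferon-stimulated gene of 30 was called, also adjusted over the list alone (camera adjusted p = 0.81). EIF2AK2 had a log2 fold change of 0.19 (adjusted p = 0.263). Of 26 p53 targets GDF15 fell 1.37-fold (4 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.94), and it was not called with GC correction (adjusted p = 0.0911). No gene of the 24 of cholesterol synthesis was called, and 1 fell adjusted over the list alone (camera adjusted p = 0.94, mean and median of opposite sign). MVD had a log2 fold change of -0.31 (adjusted p = 0.0541). None of 26 regulators of the epithelial-mesenchymal transition was called, and 2 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.94, mean below 0 and median above 0). TCF4 had a log2 fold change of 0.30 (adjusted p = 0.0549) and FOXC2 of -0.31 (adjusted p = 0.0653). Of 23 HOX genes none was called without GC correction, also adjusted over the list alone (camera adjusted p = 0.94). HOXB9 had a log2 fold change of -0.91 (adjusted p = 0.107) and HOXA13 of 0.67 (adjusted p = 0.11). Of 22 neuronal genes TUBB3 fell 1.27-fold, also as the list's 1 call when adjusted over the list alone (camera adjusted p = 0.94), but not with GC correction (adjusted p = 0.137).

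Lists that track library composition and other cell types were read as checks. Ribosomal protein genes lay slightly higher (mean 0.04, camera adjusted p = 0.048, and adjusted p = 0.94 with an estimated correlation), with none of 67 genes called, also adjusted over the list alone. RPS27 had a log2 fold change of 0.22 (adjusted p = 0.16) and RPL34 of 0.20 (adjusted p = 0.168). The ribosomal list mean relative to other genes was -0.03 without scrambled replicate 3, and the list did not pass without H3F3A siRNA replicate 1 (adjusted p = 0.678), without H3F3A siRNA replicate 3 (adjusted p = 0.124) or with numbered copies summed (adjusted p = 0.052). No oxidative phosphorylation gene of 47 was called, also adjusted over the list alone (camera adjusted p = 0.78). NDUFS8 had a log2 fold change of -0.21 (adjusted p = 0.221) and SDHB of -0.15 (adjusted p = 0.327). Of 9 endothelial markers, EGFL7 and ROBO4 fell 1.39-fold and 1.37-fold (3 adjusted over the list alone; mean -0.22, camera adjusted p = 0.015, and adjusted p = 0.39 with an estimated correlation). With GC correction none of the 9 was called and the list did not pass (adjusted p = 0.18), nor did it in the first stranded column (adjusted p = 0.261) or with no filter on low counts (adjusted p = 0.0614). Of 8 fibroblast markers PDGFRB and COL1A1 each fell 1.28-fold and PDGFRA rose, and none was called with GC correction (3 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.63, mean and median of opposite sign). None of 5 epithelial markers was called, also adjusted over the list alone (camera adjusted p = 0.7). KRT18 and KRT7 had log2 fold changes of -0.18 and -0.33 (adjusted p = 0.545 and 0.585). None of 7 immune markers was called, and 3 fell adjusted over the list alone (camera adjusted p = 0.13). CORO1A and FCER1G had log2 fold changes of -0.33 and -0.91 (adjusted p = 0.0567 and 0.118), the latter below 2 CPM in every library.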

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

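The tests of explanations in this part were chosen after the results were seen, although leaving out each library had been planned, so each explanation is a hypothesis.

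The share of reads that overlapped no annotated exon can include reads from introns and enters no comparison. It was 10.1%, 10.2% and 9.68% in H3F3A siRNA replicates 1, 2 and 3 and lay above both scrambled libraries, at 9.17% and 9.26%. The share of assigned counts in the ribosomal RNA genes RNR1 and RNR2 was also higher, at 0.604%, 0.541% and 0.55% against 0.468% and 0.499%, as was the number of genes with counts, at 23184, 23092 and 23020 against 22817 and 22930. With 10 splits of the libraries, no exact test of these differences can reach 0.05, and what they mean for the gene lists was not tested.

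More genes fell than rose after H3F3A siRNA, 427 against 80. With the GC trend of every library removed, falls still outnumbered rises, at 69.9% of calls, while the number of falls dropped to 197. The exact 95% interval (64.1% to 75.2%) is over genes, which are not independent, and does not measure the spread between libraries. It therefore cannot tell whether the GC trend was the whole cause. With scrambled replicate 1 left out, 80.4% of calls were falls. The 1 scrambled library left has no measured spread, and its own deviation can push calls one way. This share therefore cannot tell whether scrambled replicate 1 was the whole cause. Without H3F3A siRNA replicate 1, 60% of 15 calls were falls (32.3% to 83.7%), too few calls to show an excess, and without scrambled replicate 3 the share was 70% of 2481 (68.2% to 71.8%). Without H3F3A siRNA replicates 2 and 3 it was 86.4% and 82.1%. The real split called 507 genes and the highest of the other splits called 3. Of the 10 splits only the real one called that many, and 10 splits are too few for a share under 0.05. With GC correction the real split called 282 genes and the highest other split 58, which set scrambled replicate 1 and H3F3A siRNA replicate 1 against the rest. A lower H3.3 supply after the knockdown may account for part of the excess of falls and was not tested apart from the grouping itself.

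H3P6 fell with H3F3A. H3F3A siRNA libraries held 0.949 times as many H3P6 counts per H3F3A count as scrambled libraries, with a counting error of 0.089, as reads of H3F3A transcripts counted under the pseudogene would give. A candidate explanation is therefore shared reads, but an siRNA that also acts on a separate H3P6 transcript would leave the same ratio, and its sequence is not given in the sources used here.

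Extracellular matrix genes fell as a list by camera at the preset correlation, whose p-value does not measure the spread between libraries. The list did not pass with an estimated correlation (adjusted p = 0.39), a test with few degrees of freedom here, or by fry (adjusted p = 0.087). Endothelial and immune markers had similar mean log2 fold changes, -0.218 and -0.242 against -0.229, and with GC correction -0.0922 and -0.164 against -0.166. With GC correction neither marker list passed (adjusted p = 0.18 and 0.24). After GC correction the per-library means of the matrix list differed by -0.167 (SE 0.035 between libraries), which argues against the GC trend as the whole cause. Before correction the difference was -0.227 (SE 0.053). With scrambled replicate 1 left out it was -0.189, and -0.169 with GC correction as well. The 1 scrambled library left has no measured spread, so these values cannot tell whether scrambled replicate 1 was the whole cause. After GC correction, the matrix list means relative to the mean of all libraries in H3F3A siRNA replicates 1, 2 and 3 were -0.115, 0.00063 and -0.0859, all below the scrambled libraries at 0.0981 and 0.103. The knockdown may lower matrix genes, a hypothesis that these libraries cannot separate from an unlabelled difference between the cultures.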

How the results depend on the processing

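Leaving out libraries, the strand columns and the settings named in the methods were planned; the GC correction, its gene set, its combination with scrambled replicate 1 left out and the summed copies were chosen after the data were seen. The H3F3A transcript level kept its fall and its call in every alternative in which genes were tested, with log2 fold changes of -4.98 to -4.82. All 66 other called genes that the naming rule gave kept their direction. Leaving out a library could hardly turn it, as no called gene had libraries that overlapped between the groups. Of the 66 genes, 10 kept their call in each of these alternatives. Leaving out a library takes residual degrees of freedom, and without either scrambled library 1 control is assumed to vary like the H3F3A siRNA libraries. Depth limits the test at low counts: the median standard error of the log2 fold change was 0.396 in the 2721 genes under 1 CPM, of which 10 were called, and 0.0781 in the 4719 genes of at least 50 CPM. Canonical histones and epithelial, endothelial and immune markers had too few members for a test at a mean of at least 5 CPM, as had epithelial markers in the strand columns. Unless noted, the cause of a change was not tested.

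The genes changed by H3F3A siRNA, split into genes that fell and genes that rose, numbered 792 (153 rose) with no filter on low counts, 313 (270 fell, 43 rose) with a mean of at least 5 CPM, where fewer genes were tested, 19 with an absolute log2 fold change of at least 1, 282 (197 fell) with GC correction, and 72 (56 fell, 16 rose) with GC correction and scrambled 1 left out. Other tools and scalings gave 543 (RLE), 439 (upper quartile), 397 (robust=FALSE), 407 and 428 (strand columns) and 527 (DESeq2). Leaving out each library gave 15 to 2481 changed, 9 to 1737 fallen and 6 to 744 risen genes. The MCAM transcript level ranged from -0.454 to -0.333 with a library left out and lost its call at -0.317 with GC correction and scrambled 1 left out; its adjusted p ran from 3.33e-06 to 0.0848 over the alternatives. The number of lists past the threshold was 0 with an estimated correlation, 0 by fry and 5 to 9 with a library left out.

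Replicates 1 and 3 occur in both groups, but only 2 pairs exist and the labels do not say what a number marks. Deviations from the group means correlated at 0.11 for number 1 and 0.049 for number 3. The 2 scrambled libraries deviate as mirror images, so values across numbers only turn these signs and no pairing is read from these correlations. The first principal component of log2 CPM, with 37.2% of the variance, put scrambled 1 and 3 at -27.6 and -9.09. It put H3F3A siRNA 1, 2 and 3 at 13.2, 12.2 and 11.2. The second principal component, with 25% of the variance, put scrambled 1 and H3F3A siRNA 1 at 10.7 and 18.3. Scrambled 3 lay at -19, and H3F3A siRNA 2 and 3 at -6.71 and -3.27. A condition shared by the libraries numbered 1 is thus not excluded, and the fit without a block would not take it up. With the replicate block the genes changed by H3F3A siRNA numbered 574, with 356 falls and 68 rises shared with the fit without it. H3F3A siRNA 2 is the only library with its number, so that comparison rests on the 2 pairs. The block also leaves few residual degrees of freedom, so the shared calls are weak support.

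The H3F3B transcript level was not called in any alternative and changed sign around 0, to 0.0195 with upper-quartile scaling, 0.00305 with no filter, 0.00121 with a mean of at least 5 CPM, 0.00774 and 0.0178 in the strand columns, 0.0212 with the replicate block, 0.0072 with GC correction, 0.00764 over genes with a GC value, 0.0229 with GC correction and scrambled 1 left out, and -0.0356 to 0.0256 with a library left out.

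List means relative to other genes also changed sign, in lists that were not called, apart from ribosomal proteins. With no filter they were -0.0652 for PAX3-FOXO1 targets, 0.0662 for HOX genes, -0.0643 for ribosomal proteins, -0.0988 for oxidative phosphorylation, -0.15 for fibroblast and 0.493 for epithelial markers. In all of these lists the sign of the median and the direction of the test stayed as with the filter. With a mean of at least 5 CPM they were 0.0202 for myogenic regulators, 0.00474 for G1/S, 0.0319 for epithelial-mesenchymal transition, 0.00999 for p53 targets, 0.00596 for cholesterol synthesis, 0.00946 for polycomb and -0.0631 for fibroblast markers. The first strand column gave 0.00809 for epithelial-mesenchymal transition, 0.0212 for cholesterol synthesis, 0.0203 for HOX and -0.0631 for neuronal genes, and the second gave 0.04 for myogenic regulators, 0.00339 for p53 targets, 0.00271 for polycomb and -0.00313 for oxidative phosphorylation. The replicate block gave 0.00951 for myogenic regulators and 0.00185 for G1/S. GC correction gave 0.025 for myogenic regulators, -0.0104 for oxidative phosphorylation and 0.046 for epithelial markers, the genes with a GC value gave 0.0038 for myogenic regulators, and GC correction with scrambled 1 left out gave -0.0446 for H3.3 chaperones, 0.0042 for muscle differentiation and 0.0519 for epithelial markers. With a library left out the ranges were -0.0386 to 0.128 for H3.3 chaperones, -0.0245 to 0.0189 for PAX3-FOXO1 targets, -0.0258 to 0.0103 for myogenic regulators, -0.0555 to 0.00375 for G1/S, -0.074 to 0.0128 for epithelial-mesenchymal transition, -0.00239 to 0.0581 for interferon-stimulated genes, -0.0577 to 0.000744 for cholesterol synthesis, -0.0634 to 0.0203 for polycomb, -0.0278 to 0.286 for neuronal genes, -0.0337 to 0.0896 for ribosomal proteins and -0.0453 to 0.0526 for oxidative phosphorylation.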

Other observations

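The comparisons of neighbouring genes and of gene spans were chosen after the results were seen. DLK1 was the one called gene among 5 examined at its imprinted locus. DLK1, expressed from the paternal copy, fell 1.69-fold from 17.7 ± 3.06 CPM (SD, n = 2) to 10.5 ± 1.1 CPM (SD, n = 3; edgeR adjusted p = 0.00133), and its log2 fold change was -0.68 with GC correction (adjusted p = 0.00216). The DLK1 call was lost without H3F3A siRNA replicate 1 and with GC correction when scrambled replicate 1 was also left out. The maternally expressed RNA MEG3 had a log2 fold change of -0.10 (SE 0.0811, adjusted p = 0.592) at 264 CPM, and MEG8 of -0.05 (SE 0.11, adjusted p = 0.867). RTL1 and DIO3 had 0.03 (adjusted p = 0.98) and -0.42 (adjusted p = 0.251). The differences between these genes were not tested.

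The genes that rose had a median genomic span of 82.2 kb in GENCODE release 29 against 31.5 kb for all tested genes with a span and 18.3 kb for the genes that fell. With GC correction the median spans were 24.4 kb for the 85 genes that rose and 32.6 kb for the 197 that fell, and the rank correlation of fold change with span across genes, which are not independent, went from 0.20 to 0.0035.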
